A study of Arabidopsis thaliana with 18 samples.

How the data were processed

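Small RNAs were sequenced from vasculature and epidermis of Arabidopsis thaliana leaves in the wild type Col-0 and in the mutants ago1-18 and ago1-42, with 3 libraries per genotype and tissue and 18 in all. Per the labels' protocols, plants grew in soil under 12 h light and 12 h dark, Col-0 leaves came from rosettes 4-5 weeks old and mutant leaves from plants 6-8 weeks old. Total RNA was extracted with TRIzol, size-selected on a gel, made into libraries with a Lexogen small RNA kit and sequenced on an Illumina HiSeq, per the labels' protocols. How the tissues were separated is not described there. The deposited tables hold, per the file headers, each distinct sequence with its count of reads, and the values are whole numbers from 1 up for lengths of 17 to 30 nt. Bowtie2 and the genome build TAIR10 are named without a version or a role, per the submitters' processing notes, and adapter trimming and any filter by genome match are not stated.

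Samples were grouped by title. For 2 epidermis libraries the genotype label differed from the title: Col-0 replicate 3 carries the label ago1-18, and ago1-18 replicate 3 carries ago1-42. Fits grouped by the label, and fits without these 2 libraries, were run as alternatives. No batch, date or lane is given.

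Each sequence was matched without mismatches to the TAIR10 nuclear, chloroplast and mitochondrial genomes with purpose-written Python 3.11.15 code (numpy 2.4.6, pandas 2.3.3, numba 0.67.0). The highest number of genome matches of any sequence was 13335. Reads at annotated rRNA, tRNA, snRNA and snoRNA genes, with 4000 bp past the rRNA genes, and reads that also match an organelle genome were called structural or organelle reads. A read counted for a mature miRNA when both of its ends lay within 2 nt of the annotated ends; the 428 annotated mature miRNAs gave 350 features after identical sequences were merged, and 289 of these had reads. Of the guides listed from general knowledge, 74 of 74 were found, and for 39 of them an annotated opposite arm was counted as the passenger strand. Reads of 24 nt with 1 genome match were counted by their 5' end in bins of 1000 bp on the 5 nuclear chromosomes, and 607 bins at rRNA or tRNA genes were left out. Reads of 21 and 22 nt with 1 genome match were counted per gene, both strands together, in 36239 genes; miRNA, rRNA, tRNA, snRNA and snoRNA genes and genes overlapping them were left out, and trans-acting siRNA (TAS) genes were kept. Reads shared by identical copies were therefore not counted for genes, and a read in 2 overlapping genes counted for both, so that such genes are uncertain. Fragments of mRNA on the sense strand were not separated from siRNAs in these counts.

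Counts were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 after filterByExpr and TMM scaling, in a fit with 6 group means over all 18 libraries and 12 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over all features of a comparison, and a call is an adjusted p under 0.05. Every adjusted p without another name is from this test. Log2 changes carry their standard error (SE). Scaled RPM are edgeR CPM of reads after TMM scaling, so that they need not add up to the nominal total. The comparisons were vasculature against epidermis within each genotype, each mutant against Col-0 within each tissue and, for miRNAs, the difference of each mutant's tissue change from that of Col-0. A group without reads was set to a floor of 3 counts over the group, which gives "at least N-fold"; a group with 1 to 3 reads is given as a ratio with its counting interval. Libraries carry no molecular identifiers, so intervals and floors cover counting error only, and p-values measure only the spread between these samples.

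The features named were set before the data were examined: per comparison up to 10 miRNAs, 5 genes and 3 bins each way with the largest log2 change among those with an adjusted p under 0.05, a mean of at least 10 RPM in 1 of the compared groups and no overlap between the groups' replicates. To these come the fixed miRNAs miR156a, 159a, 162a, 165a, 166a, 168a, 173, 390a, 395a, 398b, 399b and 403, the TAS genes and AGO1. Further members of the lists were picked for naming after their values were seen, as were guide and passenger pairs. The result of 1 miRNA target gene is not reported here. The lists are miRNAs of AGO homeostasis (miR162, 168, 403), HD-ZIP III regulation (miR165, 166), nutrient supply, phase change and leaf growth, auxin, triggers of secondary siRNAs, young or lineage-specific families, a 5' U, a 5' A, a 5' C and passenger strands, and the TAS genes, PPR genes and miRNA target genes for 21-22-nt siRNAs. They were tested with camera (preset correlation 0.01, repeated with an estimated correlation) and fry of limma 3.58.1 on log2 CPM with a prior count of 2, adjusted over the lists of a comparison, in 99 miRNA and 21 gene list tests. Camera compares a list with the other features. The fry p asks whether a list moves, on balance, in 1 direction and its mixed p whether members change either way, and neither compares the list with other features.

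Composition shares were taken over nuclear reads of 20 to 24 nt, except the passenger share, taken over the reads of both arms, the 5' U share, taken over 21-nt reads that are no miRNA, and the chloroplast share, taken over all reads. Shares and marker levels were compared by two-sided exact permutation tests on the difference of means, with tissue labels permuted within genotypes (8000 arrangements) or genotype labels within tissues (400 arrangements), and adjusted over all tests of the kind. Within 1 stratum, 3 against 3 libraries cannot give a p below 0.1. Marker genes of mesophyll, phloem, xylem, bundle sheath, epidermis and guard cells were listed from general knowledge, and reads of 17 to 30 nt with 1 genome match on the sense strand of their exons, taken as mRNA fragments, were summed per list as RPM of nuclear reads. No gene is in more than 1 of these lists. Groups of 3 were not tested for outliers.

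The procedure was tested on simulated data drawn for Col-0 vasculature against epidermis. For 160 simulated miRNAs it recovered 20% of 2-fold, 55% of 4-fold and 100% of 16-fold changes, for 16257 bins 7.69%, 47.8% and 80.6%, and for 5017 genes 1.54%, 19.4% and 85.9%. False calls among unchanged features were 0 of 100, 3 of 16058 and 3 of 4821. Chance agreement of comparisons that share the Col-0 libraries was taken from 20 simulations of unchanged groups, in which both mutants were compared with the same simulated Col-0 libraries. Alternatives were RLE factors, the library total or the total outside structural and organelle reads as library size, the Wald test of DESeq2 1.42.0, no filter on low counts, exact mature sequences, weighted multiple matches, bins of 500 bp, antisense reads only, only the compared groups, a replicate block, each library left out in turn, other denominators and distinct sequences. Figures were drawn with matplotlib 3.10.9.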

Results

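The libraries held small RNAs of vasculature and epidermis of rosette leaves from the wild type Col-0 and from ago1-18 and ago1-42, mutants of AGO1, the main Argonaute protein that carries miRNAs in plants. Each of the 6 groups had 3 libraries. Total reads per library ran from 13249196 in ago1-42 vasculature replicate 1 to 55722580 in ago1-18 vasculature replicate 3. Structural and organelle reads took 45.7% of nuclear reads of 20 to 24 nt in ago1-42 vasculature replicate 1 and 89.2% in ago1-18 vasculature replicate 2; ago1-18 epidermis replicate 1 (88.9%) and Col-0 vasculature replicate 1 (84.4%) came next. Mature miRNA reads per library ran from 95872 (ago1-18 vasculature replicate 2) to 3550088 (Col-0 epidermis replicate 3). Uniquely matching 24-nt reads ran from 338159 (ago1-18 epidermis replicate 1) to 3293921 (Col-0 vasculature replicate 2), and 21-22-nt reads in genes from 104534 (ago1-42 vasculature replicate 1) to 503692 (Col-0 epidermis replicate 1). Replicates of a group spread beyond counting error, with a median chi-square per degree of freedom of 9.28 to 30.6 for miRNAs, 2.47 to 4.42 for 24-nt bins and 3.51 to 5.33 for genes.

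AGO1 (AT1G48410), the mutated gene, is itself a target of miR168 and gave 21-22-nt reads in every library. In Col-0 its scaled RPM were 343, 404 and 807 in vasculature and 950, 1040 and 1628 in epidermis (replicates 1, 2 and 3). In ago1-18 they were 316, 399 and 291 in vasculature and 370.0, 258 and 201 in epidermis, and in ago1-42 474, 366 and 180 in vasculature and 311, 542 and 263 in epidermis. AGO1 siRNAs were lower in ago1-18 than in Col-0 epidermis (log2 -2.12 ± 0.56 SE, adjusted p = 0.0168), a call that ended without Col-0 epidermis replicate 3 or ago1-18 epidermis replicate 2 or 3 (log2 -2.14 to -1.93). The other AGO1 comparisons did not pass. These reads do not check the mutations, since siRNAs at the locus tell neither the sequence of the alleles nor the amount of protein.

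The make-up of the libraries was compared between tissues and between genotypes. Mature miRNAs took 23.6% ± 2.92 (SD, n = 3) of nuclear reads of 20 to 24 nt in Col-0 epidermis and 4.60% ± 2.68 in Col-0 vasculature. The shares were 7.38% ± 3.91 and 1.504% ± 0.951 in ago1-18 and 10.2% ± 4.68 and 2.31% ± 0.700 in ago1-42. Passenger strands are the arms of miRNA duplexes that are usually discarded, taken here as the arms opposite the listed guides. In some families that arm held most reads in Col-0 vasculature, such as miR393 (98.4%) and miR824 (86.1%). The miR393 family took 3.81% of the reads of both arms of all families in Col-0 epidermis, 17.6% in ago1-18 and 21.3% in ago1-42 epidermis. Passenger strands took 3.02% ± 0.549 of the reads of both arms in Col-0 vasculature and 10.05% ± 2.02 in Col-0 epidermis. They took 31.6% ± 4.28 and 50.2% ± 4.27 in ago1-18 and 29.3% ± 2.52 and 43.8% ± 4.98 in ago1-42, and in each tissue all 3 libraries of each mutant lay above all 3 of Col-0. TAS siRNAs, phased siRNAs whose precursors are cut under miRNA guidance, took 0.456% ± 0.270 and 0.922% ± 0.328 in Col-0 vasculature and epidermis, 0.0383% and 0.0346% in ago1-18 and 0.0642% and 0.0878% in ago1-42. Reads of 21 nt, the size class of most miRNAs, took 18.4% of reads in Col-0 vasculature and 33.7% in epidermis, against 14.3% and 23.6% in ago1-18 and 15.9% and 24.9% in ago1-42. Reads of 24 nt, the size class that guides DNA methylation, took 34.2% and 26.8% in Col-0, 37.5% and 26.5% in ago1-18 and 37.3% and 27.7% in ago1-42.

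In two-sided exact permutation tests of 8 shares, the passenger share rose by 34.4 percentage points in ago1-18 and 30.0 in ago1-42 (exact p = 0.005 each, the smallest that 400 arrangements can give, adjusted p = 0.0133). The TAS share fell by 0.653 and 0.613 points (adjusted exact p = 0.0133 each), the miRNA share by 9.68 (adjusted p = 0.0218) and 7.87 points (adjusted p = 0.0277), and the 21-nt share by 7.07 (adjusted p = 0.0218) and 5.66 points (adjusted p = 0.0277), all by the exact test. Between tissues the miRNA share was 10.9 points, the 21-nt share 11.2 and the passenger share 13.4 points lower in vasculature (adjusted exact p = 0.0015 each, from p = 0.00025, the smallest that 8000 arrangements can give). With structural and organelle reads left out the miRNA and 21-nt shares were 32.7 and 30.8 points lower (adjusted exact p = 0.0015 each). The 5' U share of 21-nt reads outside miRNAs was 6.28 points higher in vasculature (adjusted exact p = 0.0015), but without these reads it stood at -0.759 (adjusted exact p = 0.58). The 24-nt share was 9.32 points higher (adjusted exact p = 0.0133; 22.7 points without these reads, adjusted exact p = 0.0015) and the chloroplast share 5.95 points lower (adjusted exact p = 0.042). The 22-nt share passed in no comparison, and the TAS share did not pass between tissues (adjusted exact p = 0.223). Without structural and organelle reads it was 0.362 points lower in vasculature (adjusted exact p = 0.01). In the mutants the 24-nt, 5' U and chloroplast shares did not pass, with differences of 1.47, -1.15 and 6.47 points in ago1-18 and 1.95, -0.819 and 4.18 in ago1-42. With structural and organelle reads left out, however, the 5' U share fell by 12.3 points in ago1-18 and dropped by 10.8 points in ago1-42 (adjusted exact p = 0.01 each). The miRNA share then fell by 15.4 and 10.9 points (adjusted exact p = 0.01 and 0.0171) and the 21-nt share by 12.1 (adjusted exact p = 0.0171), while its fall by 8.59 in ago1-42 did not pass (adjusted exact p = 0.0525), nor did rises of the 24-nt share by 7.54 and 6.13 (adjusted exact p = 0.162 and 0.0776).

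**Figure D1:**
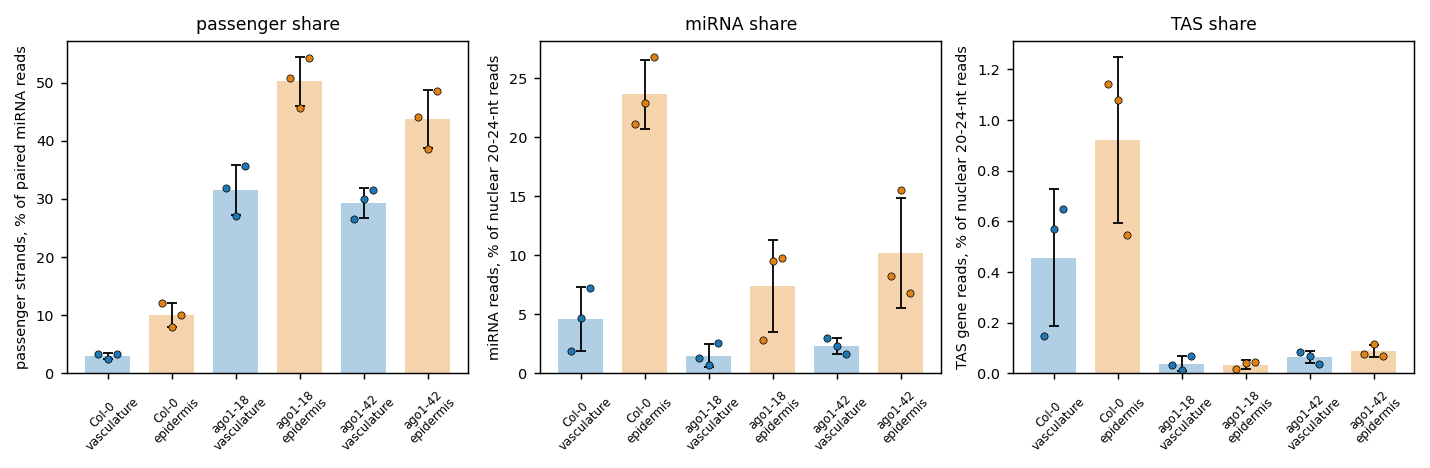
Each panel shows a share of reads in percent, with a point per library and the 6 groups of genotype and tissue along the axis. Mean passenger shares were 3.02% and 10.05% in Col-0 and 29.3% to 50.2% in the mutants.

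Fragments of cell type marker mRNAs were summed to describe the tissues. Phloem markers such as the sucrose transporter SUC2 (AT1G22710) reached 66.7 ± 5.23 RPM (SD, n = 3) in Col-0 vasculature and 6.85 in epidermis, 119 and 7.99 in ago1-18, and 129 and 7.60 in ago1-42. Epidermis markers, led by the wax synthesis gene KCS6 (AT1G68530), reached 0.518 and 286 ± 19.9 RPM in Col-0 vasculature and epidermis, 2.59 and 71.6 in ago1-18, and 2.12 and 68.3 in ago1-42. Xylem markers reached 5.06 and 0.319, 6.61 and 0.997, and 9.35 and 0.675 RPM, and the bundle sheath marker 0.635 and 0.0933, 1.42 and 0.149, and 1.69 and 0.0214. Guard cell markers reached 20.7 and 9.15 RPM in Col-0, 147 and 18.1 in ago1-18 and 50.3 and 8.57 in ago1-42. Most of these came from the myrosinase TGG1 (AT5G26000), which other leaf cells also make, with 144 RPM in ago1-18 vasculature. Phloem, xylem and bundle sheath markers were 97.5, 6.34 and 1.16 RPM higher in vasculature and epidermis markers 140.1 RPM lower (adjusted exact p = 0.00113 each); guard cell markers were 60.9 RPM higher (adjusted exact p = 0.0018). Mesophyll markers, 127 and 222 RPM in Col-0, 157 and 214 in ago1-18 and 145 and 173 in ago1-42, did not pass (adjusted exact p = 0.138). Of the mutant comparisons only the guard cell markers in ago1-18 passed, 67.8 RPM higher than Col-0 (adjusted exact p = 0.015).

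Vasculature was compared with epidermis in Col-0 to ask which small RNAs differ between the tissues. HD-ZIP III miRNAs, which restrain the transcription factors that pattern leaves and vascular strands, were lower in vasculature for 4 of 5 under each scaling: miR165a-3p stood at 3988 scaled RPM against 262361 (log2 -6.04 ± 0.72 SE, adjusted p = 1.81e-07) and miR166a-3p fell less (log2 -2.11 ± 0.44, adjusted p = 3.85e-04). Their passengers miR165a-5p (-7.31 ± 0.69) and miR166a-5p (-3.93) fell too, and miR166e-5p rose (1.44) but turned negative by the library and non-structural totals. The largest fall was that of miR171a-3p, a regulator of GRAS transcription factors, with 1.51 against 419 scaled RPM (log2 -7.65 ± 1.02, adjusted p = 1.09e-06). Of 12 auxin miRNAs 9 fell and 1 rose, among them miR393b-3p (-5.30 ± 0.58, adjusted p = 6.55e-08), miR167c-3p (-5.41), miR167a-3p (-3.44) and miR167a-5p (-2.24) against miR160a-5p (1.81). Of 12 triggers of secondary siRNAs 5 fell and 1 rose, and miR173-5p, which starts TAS1 and TAS2 siRNAs, did not differ (0.04). Of 40 passengers 14 fell and 8 rose.

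Lineage-specific miRNAs made up many of the higher ones in Col-0 vasculature. Of 87 such features 28 rose and 9 fell, but by the library total 7 rose and 16 fell. The arms miR846-3p (log2 6.34 ± 0.70 SE, adjusted p = 6.55e-08, 3702 against 45.7 scaled RPM) and miR846-5p (6.33 ± 0.63, adjusted p = 1.7e-08) and miR842 (4.64 ± 0.75, adjusted p = 1.61e-05), all from families that target jacalin lectin genes, were among the higher ones, as was miR851-5p, at least 42.9-fold higher over the floor of 3 counts in the epidermis group. With few epidermis reads, miR837-5p was higher by a ratio of 121 (counting interval 32.7 to 1017), miR837-3p by 65.8 (17.3 to 558) and miR780.2 by 85.2 (14.3 to 3465). Of 14 nutrient miRNAs 8 rose and 3 fell, yet by the library total 2 rose and 5 fell. The copper miRNA passenger miR398a-5p rose (4.56 ± 0.51, adjusted p = 7.81e-08), as did the phosphate miRNA miR399b (2.32 ± 0.65, adjusted p = 0.00555), while miR398b-3p fell (-1.51, adjusted p = 0.0122). The sulfate miRNA miR395a (1.501, adjusted p = 0.0069), miR403-3p (1.51, adjusted p = 0.00173) and miR159a (1.23, adjusted p = 0.0286) rose, but by the library total they stood at -0.20, -0.11 and -0.56. Of 27 phase and leaf growth miRNAs 6 rose, such as miR319a (3.08), and 3 fell, but by the library total none rose and 11 fell. Of 7 AGO homeostasis miRNAs 1 rose, and miR168a-5p (-0.70) and miR162a-3p (0.42) did not pass. With a 5' U 30 rose and 20 fell of 100, with a 5' A 13 and 11 of 44, and with a 5' C 4 and 1 of 18.

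Of 180 miRNAs tested in Col-0, 52 were higher and 37 lower in vasculature, and 61.1% had groups that did not overlap, against 10% by chance. Camera called the HD-ZIP III list lower (adjusted p = 0.00642; adjusted p = 0.202 with an estimated correlation), the auxin list lower (0.00357; adjusted p = 0.295 with an estimated correlation), the passenger list lower (0.0171; adjusted p = 0.370 with an estimated correlation) and the young list higher (0.00642; adjusted p = 0.202 with an estimated correlation). Adjusted over the list alone, the counts higher and lower were 2 and 9 for auxin, 8 and 4 for nutrients, 27 and 7 for young families, 3 and 0 for a 5' C and 9 and 14 for passengers. Calls ended when libraries were left out for miR159a (Col-0 vasculature replicate 1 or 3, epidermis replicate 3; log2 1.08 to 1.17), miR398b-3p (vasculature replicate 1 or 2, epidermis replicate 3; -1.19 to -0.86), miR390a-5p (-1.08; vasculature or epidermis replicate 2 or 3; -1.08 to -0.86) and miR395a (vasculature replicate 3; 1.13).

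Among 21-22-nt siRNAs of genes, TAS3 (AT3G17185), whose siRNAs restrain auxin response factors, stood at 62825 against 11916 scaled RPM in Col-0 vasculature and epidermis (log2 2.40 ± 0.55 SE, adjusted p = 0.00205); without epidermis replicate 3 the call ended (log2 1.79), as it did by the library total (1.65). By that total no TAS gene was higher and 2 were lower. TAS3b (AT5G49615) also rose (3.05 ± 0.95, adjusted p = 0.024), a call that ended without any of 5 of the 6 libraries (log2 2.46 to 3.04; it held without vasculature replicate 1). TAS1A (-1.16), TAS1B (-1.13), TAS1C (-0.45) and TAS2 (-0.35) did not pass, none of 7 PPR genes did, and of 11 miRNA targets ARF4 (AT5G60450) rose (2.48) and the auxin receptor gene AFB2 (AT3G26810) fell (-1.77). Targets numbered 1 higher and 4 lower by RLE factors and by the library total. Reads of the zinc transporter gene HMA4 (AT2G19110) were at least 27.8-fold higher in vasculature. Those of AT1G09310 and of the wax synthesis gene KCS1 (AT1G01120) were at least 159-fold and 124-fold lower and those of ELI3-1 at least 70.3-fold lower. In all, 436 of 5635 genes were higher and 291 lower, with 32.6% not overlapping. By RLE factors the counts were 257 and 409, by the library total 123 and 501 and by the non-structural total 101 and 212. No gene list passed camera, and adjusted over the list alone 1 target gene rose and 3 fell. Among 17689 bins of 24-nt reads 34 were higher and 200 lower, with 21.8% not overlapping, against 2638 and 225 by the non-structural total. Of the lower bins 172 lay in protein-coding genes, 7 between genes and 21 in other genes, where 7200, 6079 and 4410 bins were tested. The bin on chromosome 1 from 25714001 in KCS6 was at least 576-fold lower (adjusted p = 8.79e-07; at least 377-fold without Col-0 epidermis replicate 3). Sense fragments of this epidermis marker moved with it (0.226 against 202 RPM). That on chromosome 4 from 12333001 in AT4G23670 was at least 333-fold and that on chromosome 1 from 3009001 in AT1G09310 at least 295-fold lower. The higher bins at AT5G22090, the sulfate transporter gene SULTR2;1 and GTR2 (at least 27.8-fold, 26.9-fold and 19.04-fold) lost their calls when libraries were left out, each without at least 4 of the 6 in turn. Without Col-0 vasculature replicate 1 the first 2 bounds were 4.08-fold and 8.86-fold.

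The tissue comparison was repeated within the mutants. In ago1-18, miR165a-3p did not pass between the tissues (log2 0.19, adjusted p = 0.818). It was called lower in vasculature by the library total (-2.49, adjusted p = 0.008), by the non-structural total (-1.92, adjusted p = 0.0204) and grouped by genotype label (-4.06, adjusted p = 0.0179). In ago1-42 it was lower in vasculature (-2.99 ± 0.62, adjusted p = 5.58e-04). Its passenger miR165a-5p was lower in both (-3.24 ± 0.57, adjusted p = 1.17e-04, and -4.04 ± 0.58, adjusted p = 2.17e-05), as was miR393b-3p (-2.80 and -3.13). Higher in vasculature of both were miR398a-5p (5.19 ± 0.53, adjusted p = 5.13e-08, and 4.47 ± 0.51, adjusted p = 4.57e-07), miR8167a (4.27 and 3.53), miR837-3p (47.5-fold, counting interval 12.4 to 403.5, and at least 32.5-fold) and miR399b (2.72 and 2.71; in ago1-18 the call ended without vasculature replicate 3, log2 1.73). miR166a-3p passed in ago1-42 alone (-1.39, adjusted p = 0.0152, lost without vasculature replicate 2 or 3 or epidermis replicate 2, log2 -1.27 to -0.97), against -0.79 in ago1-18. miR171a-3p was lower in ago1-42 (37.3-fold, interval 12.6 to 182) and miR170-5p at least 7.47-fold lower. miR846-3p rose in ago1-18 (2.38) and did not pass in ago1-42 (0.95). miR403-3p rose in ago1-18 (1.09, adjusted p = 0.0279, lost without any of 5 of its 6 libraries, log2 0.96 to 1.15, held without vasculature replicate 3; -1.08 by the library total) and not in ago1-42 (-0.05). In ago1-42, miR397a was at least 15.5-fold higher and miR397b rose (3.74), against 3.91 and 2.81 in ago1-18, which did not pass.

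By list, of 14 nutrient miRNAs 4 rose and 1 fell in ago1-18 and 6 and 1 in ago1-42, and of 87 young ones 19 and 3, and 22 and 12; by the library total 1 nutrient miRNA rose and 4 fell in ago1-18, 2 and 3 in ago1-42, and 3 young ones rose and 13 fell, and 3 and 17. Of 5 HD-ZIP III miRNAs 1 rose and 2 fell in ago1-18 and 1 and 4 in ago1-42, and by the library total none rose and 4 fell in each. Auxin miRNAs numbered 1 higher and 2 lower in each mutant, triggers 0 and 1 in each, AGO homeostasis 1 and 0 in each, phase and leaf growth 2 and 2, and 2 and 3, passengers 7 and 9, and 9 and 8. With a 5' A 13 rose and 7 fell in ago1-18 and 15 and 6 in ago1-42, with a 5' C 2 and 0, and 4 and 0, and with a 5' U 12 and 3, and 13 and 18, against 0 and 32, and 3 and 32, by the library total. Camera passed no miRNA list in ago1-18 (smallest adjusted p = 0.107) and the 5' U list as lower in ago1-42 (adjusted p = 0.0444; adjusted p = 0.536 with an estimated correlation). Adjusted over the list alone, nutrient miRNAs numbered 8 higher and 1 lower and 5' A miRNAs 15 and 7 in ago1-18, and young ones 24 and 12 and 5' A ones 16 and 6 in ago1-42. Of 180 miRNAs 31 were higher and 13 lower in ago1-18 (41.7% not overlapping) and 38 and 26 in ago1-42 (39.4%). RLE factors gave 29 and 20, and 30 and 34.

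TAS and PPR siRNAs were compared between tissues in the mutants too. In ago1-42 vasculature 6 of 7 TAS genes were lower than in epidermis, among them TAS2 (log2 -3.91, adjusted p = 4.08e-06), TAS1B (-3.997, adjusted p = 7.84e-06) and TAS1A (-3.33, adjusted p = 3.54e-05), and 3 of 7 PPR genes fell, such as AT1G62930 (-4.66) and AT1G63150 (-3.94). TAS1C (-1.74, adjusted p = 0.0316) ended without vasculature replicate 1 or 3 or epidermis replicate 2 or 3 (log2 -1.74 to -1.50), and TAS3b (-4.71) without epidermis replicate 2 (-1.96). The call of AT3G25795, also among the 6, was lost without any vasculature library (-6.50 to -6.44) and without epidermis replicate 2, which held its reads (0.00). TAS3 did not pass (1.495, adjusted p = 0.0699). In ago1-18 TAS3 alone rose (1.72 ± 0.54, adjusted p = 0.038), a call lost without any of 5 of the 6 libraries (log2 1.13 to 1.95; it held without vasculature replicate 2) and under each of the 3 other scalings. No PPR gene passed there. The miRNA targets numbered 0 higher and 0 lower in ago1-18 and 1 and 2 in ago1-42, where PHB reads rose (4.59) and those of AFB2 (-1.83) and AFB3 (-2.48) fell. The difference of these tissue changes between genotypes was not tested for genes. Camera called TAS (adjusted p = 1.53e-04; adjusted p = 0.116 with an estimated correlation) and PPR genes lower in ago1-42 (4.04e-04; adjusted p = 0.116 with an estimated correlation). Adjusted over the list alone, TAS genes numbered 1 higher and 2 lower in ago1-18 and 1 and 6 in ago1-42, and PPR genes 0 and 5 in ago1-42. Of 5635 genes 272 were higher and 147 lower in ago1-18 (25.4% not overlapping) and 258 and 253 in ago1-42 (25.3%), with 201 and 198, and 225 and 335, by RLE factors. Reads of BCAT4 were higher by 387-fold (interval 69.2 to 15324) and those of WRKY46 at least 15.2-fold in ago1-18. With 0.636% and 0% of them antisense they may be mRNA fragments. There ATML1, a gene of epidermal identity, was at least 20.95-fold and ABCB2 at least 23.9-fold lower. ATML1 (AT4G21750) had 2.31% antisense reads and is also an epidermis marker, whose sense fragments stood at 0.0851 against 3.16 RPM. The median antisense share was 1.04% for the genes higher in ago1-18 vasculature, against 6.93% for all genes tested. In ago1-42 PHO1;H1, a homologue of the phosphate exporter PHO1, was at least 26.9-fold higher, and PIRL2 (AT3G26500) at least 125-fold (32.8-fold without epidermis replicate 2), the lipid transfer gene LTPG1 at least 35.7-fold and ELI3-1 at least 31.4-fold lower.

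Among 24-nt bins, 28 were higher and 60 lower in vasculature of ago1-18 (19.8% not overlapping) and 196 and 357 in ago1-42 (22.1%). Of the lower ones 43 and 179 lay in protein-coding genes and 6 and 127 between genes. In ago1-18 the bin in PRP4 on chromosome 4 from 18098001 was lower by 379-fold (interval 66.4 to 15106). In ago1-42 the bin on chromosome 1 from 17641001 at AT1G47880 was at least 1342-fold and that on chromosome 2 from 11045001 at AT2G25905 at least 1017-fold lower. The first had 0 reads in the vasculature libraries and 14.8, 2528 and 112 scaled RPM in the epidermis replicates 1, 2 and 3, and the other 14.8, 1842 and 153. Without epidermis replicate 2 the bounds were 95.98-fold and 127-fold. The ago1-42 calls numbered 142 without epidermis replicate 2. By the non-structural total the counts were 102 and 47 in ago1-18 and 1043 and 241 in ago1-42.

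Tissue calls recurred across the genotypes. In all 3 genotypes 23 miRNAs were higher and 11 lower in vasculature, with 116 and 80 genes and 3 and 44 bins. Between Col-0 and ago1-18, 29 miRNAs were higher in both (8.96 for independent lists) and 13 lower (2.67); between Col-0 and ago1-42 27 (10.98) and 17 (5.34); and between the mutants 24 (6.54) and 11 (1.88). For genes the shared higher calls of these pairs numbered 157, 144 and 165 (21.05, 19.96 and 12.5 for independent lists) and the lower ones 111, 131 and 101 (7.59, 13.1 and 6.60).

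The mutant ago1-18 was set against Col-0 in each tissue. Both mutants' plants were older than Col-0, so age and genotype cannot be separated. The sulfate miRNA miR395a rose from 390.2 to 26332 scaled RPM in vasculature (log2 6.08 ± 0.53 SE, adjusted p = 1.79e-09) and by 6.54 ± 0.54 in epidermis (adjusted p = 5.54e-10), and miR395b rose by 4.48 and 5.12. Many of the other rises were passengers, such as miR164c-3p (5.88 ± 0.63, adjusted p = 3.45e-08, and 5.85), miR167a-3p (5.80 ± 0.54, adjusted p = 3.57e-09, and 2.89), miR391-3p (4.96 and 2.20), miR172b-5p (4.64 and 3.26) and miR171c-5p (4.85 and 3.10). miR160c-3p rose too (4.93 and 5.10) but stood at -0.26 in vasculature with exact sequences. Guides and passengers of a duplex could part: miR472-3p, which targets disease resistance genes, fell by 3.87 and 2.92 while miR472-5p rose by 2.67 and 1.60, and miR396b-5p fell by 2.67 and 2.22 while miR396b-3p rose by 2.93 and 2.73. miR158a-3p fell from 212163 to 11429 scaled RPM in vasculature (-4.21 ± 0.46, adjusted p = 3.45e-08) and by 4.16 in epidermis. miR403-3p, which targets AGO2, fell in both tissues (-3.53 ± 0.40, adjusted p = 6.5e-08, and -3.10, adjusted p = 4.46e-07). miR5652 was at least 26.9-fold and 36.3-fold lower, and miR164a (-2.43 and -2.11) and miR319c (-2.79 and -3.90) fell.

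Of the HD-ZIP III miRNAs, miR165a-3p fell in ago1-18 epidermis from 262361 to 5814 scaled RPM (log2 -5.50 ± 0.70, adjusted p = 4.46e-07) and miR166a-3p by 3.16 (adjusted p = 5.17e-06). The epidermis marker sum, mostly KCS6, was 71.6 RPM in these libraries against 286 in Col-0, without overlap. The test over both tissues (adjusted exact p = 0.132) could hardly pass. Marker levels in vasculature were near 0 (0.518 RPM in Col-0 and 2.59 in ago1-18), which left in effect 3 against 3 epidermis libraries. A changed cell make-up stays open. In vasculature miR166a-3p fell by 1.83 (adjusted p = 0.00161), and miR165a-3p did not pass (0.74; -0.31 by the library total). Its tissue difference is tested among the interactions. Of the AGO homeostasis miRNAs, miR162a-3p fell in vasculature (-1.47, adjusted p = 0.0131, lost without ago1-18 vasculature replicate 2 or 3, log2 -1.31 to -1.29) and in epidermis (-1.81, adjusted p = 0.00254), while its passenger miR162a-5p rose (3.22 and 2.45). miR168a-5p fell in epidermis (-1.25, adjusted p = 0.0286), a call lost without Col-0 epidermis replicate 1 or 3 or ago1-18 epidermis replicate 1 or 3 (log2 -1.32 to -1.09), and did not pass in vasculature (0.44; -0.38 by the library total). miR390a-5p (0.59 and 0.22), miR156a-5p (-0.45 and -0.60), miR173-5p (-3.03, adjusted p = 0.0654, and -2.53, adjusted p = 0.0864) and miR399b (1.25 and 0.85) did not pass. miR159a fell in vasculature (-1.15, adjusted p = 0.0496, lost without Col-0 vasculature replicate 1 or 3 or ago1-18 vasculature replicate 1 or 2, log2 -1.11 to -0.98). miR398b-3p fell in epidermis (-1.60, adjusted p = 0.0101, lost without Col-0 epidermis replicate 3 or ago1-18 epidermis replicate 1, log2 -1.48 to -1.03).

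The mutant ago1-42 was compared with Col-0 in the same way. miR395a rose from 390.2 to 11998 scaled RPM in vasculature (log2 4.94 ± 0.50 SE, adjusted p = 3.72e-08) and by 6.44 ± 0.54 in epidermis (adjusted p = 7.06e-10), with miR164c-3p (5.70 ± 0.63, adjusted p = 5.89e-08, and 4.85), miR172b-5p (5.44 and 3.08), miR167a-3p (5.02 and 2.06) and miR393b-3p (3.69 and 1.52). miR160c-3p (3.72 and 4.28) stood at -0.72 and -0.89 with exact sequences. miR472-3p fell by 3.80 and 2.16 against a rise of miR472-5p by 2.88 and 1.51, and miR396b-5p by 1.93 and 1.31 against 3.16 and 1.93 for miR396b-3p. miR403-3p fell in both tissues (-3.50 ± 0.40, adjusted p = 1.01e-07, and -1.94 ± 0.37, adjusted p = 2.9e-04), as did miR158a-3p (-4.15 and -2.42) and miR822-5p (-2.12 and -3.69). miR173-5p was at least 14.2-fold lower in vasculature (adjusted p = 0.00321) and did not pass in epidermis (-2.69). In epidermis miR165a-3p fell by 3.33 ± 0.63 (adjusted p = 2.69e-04) and miR166a-3p by 2.04 (adjusted p = 8.59e-04). Epidermis markers were at 68.3 RPM there against 286 in Col-0, without overlap. Their test over both tissues (adjusted exact p = 0.132) could hardly pass, since levels near 0 in vasculature left in effect 3 against 3 libraries. In vasculature miR166a-3p fell by 1.31 (adjusted p = 0.0169, lost without Col-0 vasculature replicate 3 or ago1-42 vasculature replicate 2 or 3, log2 -1.21 to -1.03) and miR165a-3p did not pass (-0.28). miR159a fell in vasculature (-1.73, adjusted p = 0.00361). miR168a-5p fell in epidermis (-1.29, adjusted p = 0.0244), lost without any Col-0 epidermis library or ago1-42 epidermis replicate 3 (log2 -1.36 to -0.91), and did not pass in vasculature (-0.02). miR162a-3p (-0.74 and -0.93), miR390a-5p (0.70 and 0.45) and miR398b-3p (0.01 and -0.76) did not pass.

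By list, passengers rose over falls by 21 to 1 and 18 to 2 of 40 in ago1-18 vasculature and epidermis and by 19 to 1 and 19 to 2 in ago1-42, while 5' U miRNAs, the kind AGO1 prefers, numbered 8 higher and 28 lower, 6 and 33, 10 and 29, and 12 and 25 of 100; by the non-structural total the last was 15 and 16. Of 44 miRNAs with a 5' A 17, 9, 14 and 9 rose and 0, 1, 0 and 1 fell, and of 18 with a 5' C 5, 5, 6 and 6 rose and 2, 1, 2 and 0 fell. Auxin miRNAs numbered 6 higher and 0 lower, 3 and 1, 7 and 0, and 4 and 1 of 12; nutrient ones 8 and 1, 5 and 1, 5 and 1, and 5 and 1 of 14; HD-ZIP III ones 1 and 1, 0 and 3, 1 and 1, and 0 and 3 of 5. Young miRNAs numbered 8 and 15, 4 and 15, 7 and 14, and 9 and 10 of 87, and by the non-structural total the last was 11 and 8. Phase and leaf growth miRNAs numbered 6 and 4, 7 and 5, 7 and 6, and 7 and 4 of 27, triggers 3 and 3, 2 and 4, 3 and 4, and 3 and 3 of 12, and AGO homeostasis ones 1 and 2, 1 and 3, 1 and 1, and 1 and 2 of 7; none of these 3 lists passed camera. Of 180 miRNAs 37 were higher and 30 lower in ago1-18 vasculature (57.8% not overlapping), 27 and 36 in its epidermis (52.2%), 36 and 31 in ago1-42 vasculature (48.3%) and 33 and 27 in its epidermis (43.3%).

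Camera called passengers higher in the same order (adjusted p = 2.55e-06, 1.22e-04, 2.52e-07 and 0.00216; adjusted p = 0.0570, 0.146, 0.0340 and 0.206 with an estimated correlation) and 5' U miRNAs lower (1.01e-08, 1.17e-05, 5.19e-08 and 7.73e-04; adjusted p = 0.00488, 0.0311, 0.00723 and 0.119 with an estimated correlation). The 5' A list passed as higher in 3 comparisons (6.46e-04, 0.0375 and 0.0025; adjusted p = 0.172, 0.329 and 0.15 with an estimated correlation) and not in ago1-42 epidermis (0.112). The 5' C list passed as higher in epidermis (0.0375 and 0.0319) and the auxin list in vasculature (0.0013 and 0.00127). So did the nutrient list in ago1-42 vasculature (0.0359). These lists and the 5' A list share members with the passenger list, such as miR167a-3p, miR393b-3p and miR160c-3p. Their results are not independent of the passengers'. HD-ZIP III miRNAs passed as lower in epidermis (0.0375 and 0.0319) and young miRNAs in vasculature (0.0263 and 0.00298). With an estimated correlation camera passed none of the 5' C, auxin, nutrient, HD-ZIP III and young calls (adjusted p = 0.134 to 0.368). For young miRNAs in ago1-18 vasculature the median was above 0 while the mean and the test were below. Of 37 calls in the 99 miRNA list tests 4 held with an estimated correlation, the 5' U list in all but ago1-42 epidermis and passengers in ago1-42 vasculature. Adjusted over the list alone, passengers numbered 24 higher and 2 lower, 18 and 4, 21 and 1, and 21 and 3, 5' U miRNAs 11 and 29, 7 and 33, 10 and 29, and 12 and 26, auxin miRNAs 8 and 0 in ago1-18 vasculature, HD-ZIP III ones 0 and 4 in ago1-18 epidermis, nutrient ones 7 and 1 in ago1-42 vasculature and young ones 4 and 13 in ago1-18 vasculature.

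Passenger shares rose in most families. Of 23 families with at least 20 reads in every library, 17 had a higher mean share in both mutants in both tissues. The miR396 passenger share was 15.8% and 30.2% in Col-0 vasculature and epidermis, 85.9% and 87.2% in ago1-18 and 70.5% and 64.7% in ago1-42. That of miR472 was 9.22% and 34.2%, 88.5% and 92.2%, and 90.3% and 86.0%, that of miR162 3.75% and 5.59%, 49.8% and 52.2%, and 37.6% and 38.6%, and that of miR164 1.09% and 3.17%, 28.7% and 48.9%, and 25.8% and 31.1%. The exceptions were miR159, miR168, miR169, miR390 (which AGO7 carries, 0.238% to 0.388%), miR408 and miR822. Families were not tested singly.

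TAS and PPR siRNAs were lower in both mutants. TAS2 fell by 7.60 ± 0.68 in ago1-18 vasculature (log2, SE; adjusted p = 1.17e-11), by 7.16 in its epidermis (adjusted p = 5.13e-11), by 7.09 in ago1-42 vasculature (adjusted p = 6.49e-11) and by 3.53 in its epidermis (adjusted p = 3.33e-05). TAS1A fell in the same order (-6.99 ± 0.66, -6.77, -6.37 and -4.20), from 12163 to 94.9 scaled RPM in ago1-18 vasculature, as did TAS1B (-7.41, -6.89, -6.48 and -3.61) and TAS1C (-4.80, -4.45, -4.34 and -3.05). TAS3, which miR390 starts through AGO7, did not pass (-1.50, -0.82, -1.33 and -0.42; the last stood at 0.13 by the non-structural total). TAS3b fell in vasculature of both mutants (-4.45, adjusted p = 0.0139, and -4.13, adjusted p = 0.0175), each lost without 3 or 4 of the 6 libraries in turn (log2 -4.40 to -3.46), did not pass in ago1-18 epidermis (-1.21) and rose in ago1-42 epidermis (3.63, adjusted p = 0.021), a call lost without ago1-42 epidermis replicate 2 (log2 0.85) or any Col-0 epidermis library. All 7 PPR genes, many of them targets of TAS2 siRNAs and miR161, fell in the 4 comparisons. By the non-structural total 6 passed in ago1-18 vasculature and 4 in ago1-42 epidermis. AT1G63080 fell from 2974 and 5456 scaled RPM in Col-0 to 24.4 and 87.2 in ago1-18 and 20.9 and 314 in ago1-42, and AT1G63150 by log2 values of -6.99, -6.90, -7.03 and -3.31. Reads that PPR copies share were not counted, so the single PPR genes are uncertain.

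Among 11 miRNA targets 5, 5, 4 and 4 fell and none rose. AFB2 (-4.34, -4.77, -3.77 and -3.71), AFB3 (AT1G12820; -4.13, -5.03, -4.21 and -3.42) and ARF4 (-4.48, -3.45, -4.40 and -2.67) fell. ARF3 passed in ago1-18 vasculature alone (-3.15, against -1.79, -2.67 and -0.06), and TIR1 (-0.94, -1.91, -1.74 and -1.90) did not pass. Camera called TAS (adjusted p = 2.22e-24, 3.05e-13, 1.14e-19 and 1.34e-05; adjusted p = 2.51e-04, 0.00347, 6.68e-04 and 0.0418 with an estimated correlation) and PPR genes lower (1.83e-33, 1.94e-22, 6.01e-32 and 4.55e-16; adjusted p = 9.05e-05, 6.15e-04, 1.14e-04 and 0.00264 with an estimated correlation), and the miRNA targets held too (adjusted p = 0.00266, 0.00806, 0.00663 and 0.0173 with an estimated correlation). Of 7 TAS genes 5, 4, 5 and 4 fell and only TAS3b rose; adjusted over the list alone, 7, 5, 7 and 4 fell, and 5, 6, 6 and 7 targets. In 5635 genes the counts higher and lower were 20 and 51 (16.1% not overlapping), 70 and 138 (24.1%), 9 and 73 (13.2%) and 56 and 103 (24.2%).

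**Figure D2:**
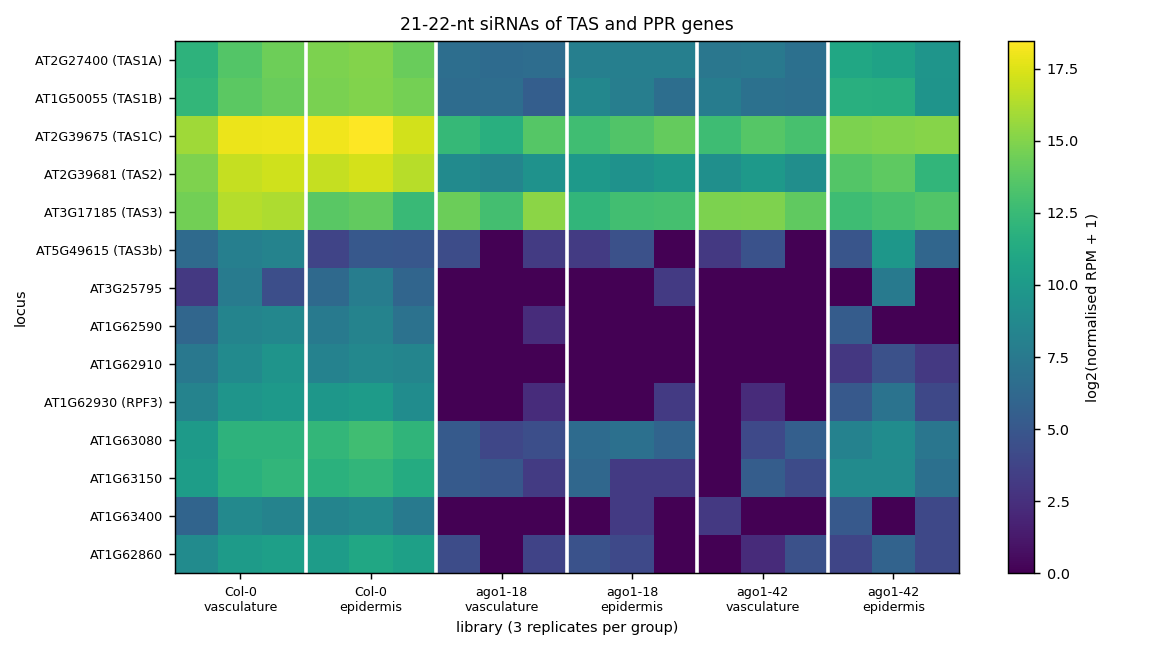
The heat map gives scaled RPM of 21-22-nt siRNAs on a log scale for TAS and PPR genes, one row per locus and one column per library in 6 groups. TAS1A averaged 12163 scaled RPM in Col-0 vasculature and 94.9 in ago1-18 vasculature.

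Other genes changed in the mutants as well. Reads of 21-22 nt at AT1G17545 were at least 77.8-fold and at AT3G50808 at least 40.7-fold higher in ago1-18 vasculature, and at least 83.5-fold and 45.7-fold higher in epidermis, where those of PCK2 (AT5G65690) were at least 75.0-fold higher. In ago1-42 vasculature the jasmonate-induced genes VSP1 (log2 5.50 ± 0.75, adjusted p = 5.1e-07) and VSP2 (3.63 ± 0.61, adjusted p = 3.95e-05) rose, and AT3G50808 was at least 21.96-fold higher, as it was in epidermis (at least 19.04-fold; 6.54-fold without ago1-42 epidermis replicate 1). Those of AT3G09960 were at least 109-fold and 112-fold lower in vasculature of ago1-18 and ago1-42, those of AT1G62914 at least 458-fold lower in ago1-18 epidermis, and those of the overlapping AT1G63615 and AT1G63630 at least 123-fold and 127-fold lower in vasculature, where the reads of each cannot be told from the other's. Without Col-0 vasculature replicate 3 these vasculature bounds were 68.7-fold and 70.7-fold for AT3G09960 and 80.6-fold and 82.9-fold for AT1G63615 and AT1G63630. The median antisense share of the genes called lower was 35.1%, 4.01%, 39.4% and 11.6% in the 4 comparisons and of those called higher 3.70%, 12.9%, 1.03% and 45.2%, against 6.93% for all genes tested. Of 17689 bins of 24-nt reads 186 were higher and 135 lower in ago1-18 vasculature (24.1% not overlapping), 201 and 147 in its epidermis (17.6%), 122 and 242 in ago1-42 vasculature (20.4%) and 228 and 236 in its epidermis (16.8%). By the non-structural total 428 and 58 were called in ago1-18 epidermis and 316 and 130 in ago1-42 epidermis. The bin on chromosome 3 from 22665001 at PLIM2c was at least 164-fold higher in ago1-18 epidermis and at least 397-fold and 126-fold higher in ago1-42 vasculature and epidermis (the last 80.98-fold without ago1-42 epidermis replicate 3). The bin on chromosome 5 from 1754001 at AT5G05820 was at least 743-fold, 147-fold and 571-fold lower in ago1-18 vasculature and epidermis and ago1-42 vasculature, and that on chromosome 1 from 6033001 at AT1G17545 higher by 2808-fold (interval 777 to 23195) and 2316-fold (415 to 91551) in ago1-18.

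The mutants were then set against each other through their Col-0 comparisons. The log2 changes of miRNAs correlated across miRNAs with r = 0.862 in vasculature and 0.706 in epidermis, against 0.455 and 0.432 in simulations without effects that share the controls, with a covariance of 5.71 and 3.87 against 0.433 and 0.2998; miRNAs are not independent replicates. Both mutants were higher for 30 and 24 miRNAs (7.4 and 4.95 for independent lists) and lower for 26 and 24 (5.17 and 5.4). For genes r was 0.721 and 0.669 (0.508 and 0.449 simulated), the covariance 1.18 and 1.54 (0.437 and 0.404), and 43 and 69 genes were lower in both (0.661 and 2.52 for independent lists), 9 and 39 higher (0.0319 and 0.696). Part of the excess may come from the shared Col-0 libraries, since 3 controls cannot be split.

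The interaction test asked whether the tissue change of a miRNA differed between a mutant and Col-0. The tissue change of miR165a-3p was 6.23 ± 0.88 log2 units higher in ago1-18 (adjusted p = 2.92e-05) and 3.05 ± 0.83 higher in ago1-42 (adjusted p = 0.0183), and that of miR846-3p differed by -3.96 and by -5.39 ± 0.84 (adjusted p = 1.49e-04 in ago1-42). miR165a-5p (4.07 and 3.27) and miR167a-3p (2.91 and 2.97) also differed in both mutants. In ago1-18 8 miRNAs had a higher and 3 a lower tissue change, in ago1-42 8 and 13, and 8 were shared; 27 and 49 had an unadjusted p under 0.05. By list, HD-ZIP III miRNAs numbered 2 higher and 0 lower in each mutant (camera adjusted p = 0.00243 and 0.0113) and auxin ones 3 and 0, and 4 and 0 (0.00266 and 0.00309). Passengers (4 and 1, 5 and 1; 0.0497 and 0.00145) and 5' A miRNAs (2 and 0 each; 0.0497 and 0.0244) passed as higher. Young (1 and 3, 0 and 9; 0.0462 and 0.00309) and 5' U miRNAs (4 and 2, 3 and 12; 0.0497 and 0.00366) passed as lower. With an estimated correlation camera passed none (adjusted p = 0.140 to 0.388). Unlike the rest of the 9 young ones, miR780.2, miR851-5p, miR839-5p and miR8183 stood out in ago1-42 epidermis replicate 2. They held 637, 122, 411 and 75.8 scaled RPM there and 0 to 22.4 in replicates 1 and 3.

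**Figure D3:**
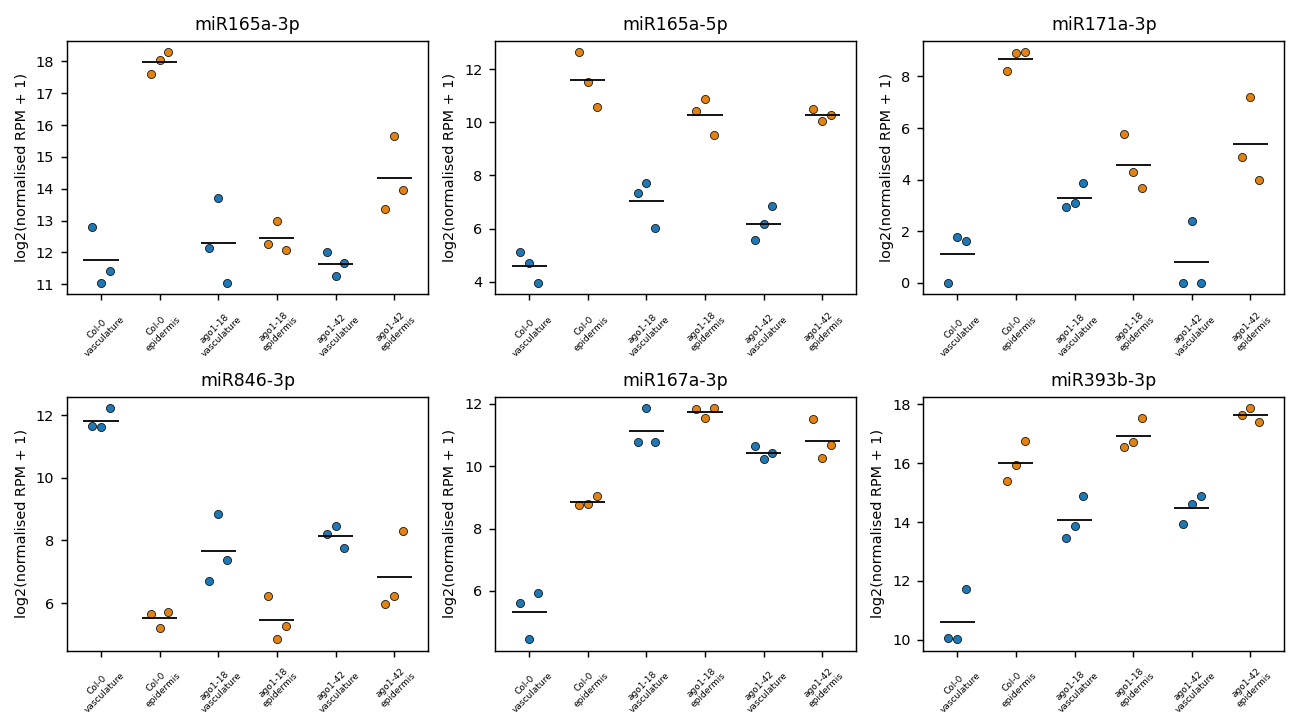
Points give log2 of scaled RPM plus 1 per library for miRNAs whose tissue change differed between a mutant and Col-0, by genotype and tissue. For miR165a-3p, Col-0 epidermis averaged 262361 scaled RPM and the other groups 3283 to 26154.

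Scaling moved the median of all features. Against TMM, RLE factors shifted the median log2 of miRNAs by 0.02, -0.38 and -0.32 in the tissue comparisons of Col-0, ago1-18 and ago1-42, by -0.45 and -0.10 in ago1-18 vasculature and epidermis, by -0.36 and -0.20 in ago1-42 and by -0.34 and -0.23 in the interactions. The library total shifted it by -1.61, -2.06, -1.31, -0.98, -0.52, 0.21, -0.40, -0.30 and 0.50 in the same order and the non-structural total by -1.46, -2.18, -1.75, -0.58, 0.29, 0.10, 0.37, -0.76 and -0.27. For genes RLE factors shifted it by -0.33, -0.33, -0.21, 0.12, 0.09, 0.15 and 0.00 in the 7 comparisons, the library total by -0.73, -0.33, 0.26, 0.17, -0.19, 0.68 and -0.27 and the non-structural total by -0.18, -0.47, -0.25, 0.57, 0.81, 0.51 and 0.52. For 24-nt bins the library total shifted it by 0.74, 0.90, 1.28, -0.14, -0.32, 0.12 and -0.40 and the non-structural total by 0.98, 0.54, 0.66, 0.10, 0.53, 0.10 and 0.43. The higher and lower miRNAs by the library total were 9 and 61, 4 and 55, and 7 and 43 between tissues, 17 and 39 and 16 and 35 in ago1-18 vasculature and epidermis, and 3 and 2 in the ago1-18 interaction. By the non-structural total they were 15 and 69, 3 and 83, and 9 and 90 between tissues, 26 and 40 and 29 and 25 in ago1-18, 39 and 17 in ago1-42 epidermis, and 3 and 3 and 4 and 13 in the interactions; RLE factors gave 27 and 41 in ago1-18 vasculature. Genes by the library total numbered 150 and 168 in ago1-18 and 319 and 206 in ago1-42 between tissues, 15 and 54 in ago1-42 vasculature and 48 and 148 in its epidermis. By the non-structural total they numbered 42 and 98 and 76 and 159 between tissues, 70 and 33 in ago1-18 epidermis and 54 and 27 in ago1-42 epidermis, and bins by the library total 67 and 55 in ago1-18 and 245 and 139 in ago1-42 between tissues.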

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

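The tests for a few genes taking most counts, plant age, depth or structural RNA, vascular RNA in epidermis libraries and epidermal RNA in vasculature libraries were chosen after the result was seen, while those for shifted ends, a strain variant, a mislabelled sample and other splits were chosen before.

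A difference between groups drew attention to 32 miRNA values (8 miRNAs in both mutants), whose edgeR test of mutant minus Col-0 tissue change passed. In ago1-18 the log2 differences were 6.23 for miR165a-3p, 6.22 for miR171a-3p, 4.07 for miR165a-5p, -3.96 for miR846-3p, 2.91 for miR167a-3p, -2.79 for miR846-5p, 2.75 for miR391-3p, 2.71 for miR822-5p, 2.50 for miR393b-3p, 2.36 for miR167d and -2.25 for miR833a-5p. In ago1-42 they were -15.44 for miR851-5p, -12.83 for miR771, -11.27 for miR780.2, -5.74 for miR394a, -5.39 for miR846-3p, -5.04 for miR8183, -4.97 for miR839-5p, -4.05 for miR846-5p, -3.63 for miR5654-3p and -3.30 for miR869.2. The remaining ones in ago1-42 were 3.27 for miR165a-5p, 3.12 for miR391-3p, 3.05 for miR165a-3p, 2.97 for miR167a-3p, 2.47 for miR167d, -2.20 for miR159a, 2.17 for miR393b-3p, 2.09 for miR168a-3p, 1.89 for miR167a-5p, -1.74 for miR158a-3p and -1.57 for miR403-3p. The fitted values of miR851-5p and miR771 involve groups without reads, depend on the prior count and are no bounds, and miR780.2 had reads in only 1 library of Col-0 epidermis and 1 of ago1-42 vasculature. Both mutants shared 8 of these miRNAs.

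Single libraries decided part of these calls. In ago1-18, miR171a-3p was lost without ago1-18 vasculature replicate 3 (5.66), miR846-5p without Col-0 epidermis replicate 1, Col-0 vasculature replicate 3 or ago1-18 epidermis replicate 1 (-2.74 to -2.07), and miR833a-5p without Col-0 epidermis replicate 2 or 3, Col-0 vasculature replicate 3 or ago1-18 epidermis replicate 1 (-2.30 to -1.91). miR167d was lost without Col-0 vasculature replicate 1 or 2, Col-0 epidermis replicate 3 or ago1-18 epidermis replicate 1 or 2 (2.02 to 2.19), and miR393b-3p without any of these or ago1-18 vasculature replicate 3 (1.88 to 2.29). miR391-3p held only without Col-0 epidermis replicate 2, Col-0 vasculature replicate 3 or ago1-18 vasculature replicate 1 (2.06 to 2.75 without the others). In ago1-42, miR771 was lost without Col-0 vasculature replicate 2 (-12.28), miR8183 (-1.82) and miR851-5p (-9.51) without ago1-42 epidermis replicate 2, and miR167d without ago1-42 vasculature or epidermis replicate 3 (1.86 to 2.11). miR5654-3p was lost without Col-0 vasculature replicate 3, ago1-42 epidermis replicate 1 or vasculature replicate 2 (-3.32 to -2.79), and miR159a without Col-0 vasculature replicate 1 or 3, Col-0 epidermis replicate 3 or ago1-42 vasculature replicate 3 (-2.35 to -2.02). miR394a was lost without Col-0 epidermis replicate 2 or 3, Col-0 vasculature replicate 3, ago1-42 epidermis replicate 2 or vasculature replicate 3 (-5.95 to -3.03), and miR869.2 without Col-0 vasculature replicate 1, Col-0 epidermis replicate 1 or 2 or ago1-42 vasculature replicate 2 or 3 (-3.23 to -2.97). miR839-5p held only without Col-0 vasculature replicate 2 or ago1-42 vasculature replicate 1, epidermis replicate 1 or 3 (-5.37 to -1.46 without the others). miR167a-5p held only without Col-0 vasculature replicate 3, ago1-42 epidermis replicate 1 or vasculature replicate 2 (1.30 to 1.97), and miR393b-3p only without Col-0 epidermis replicate 1, Col-0 vasculature replicate 3 or ago1-42 epidermis replicate 2 (1.55 to 2.21). miR403-3p held only without Col-0 vasculature replicate 1, ago1-42 vasculature replicate 1 or epidermis replicate 3 (-1.78 to -1.33), and miR168a-3p only without ago1-42 vasculature replicate 2 (0.75 to 2.29).

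In the first pattern, passenger strands took a larger share of miRNA reads in both mutants. Against a few genes taking most of the counts, 73.9% of 23 families had a higher mean share in both mutants in both tissues, and against shifted ends counted as passengers, exact mature sequences left a gap of 14.6 points between the lowest mutant and the highest Col-0 library in the tissue with the smaller gap. Plant age cannot be told apart from genotype, since 0 mutant libraries overlap Col-0 in age. An effect of the AGO1 mutations stays open and was not tested.

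In the second pattern, 21-22-nt siRNAs of TAS and PPR genes were lower in both mutants. Against a difference in depth or structural RNA, the lowest Col-0 library still held 3.80 times the TAS share of the highest mutant library in epidermis and 4.60 times in vasculature once structural reads were left out. Against a strain variant that took the chromosome segment of the PPR genes (chromosome 1, 23176930 to 23509484), at most 5.88% of 34 tested 24-nt bins there were lower in any mutant comparison, with medians of -0.39 to 0.08. This exceeds the 0.763% to 1.37% of all bins, so that smaller variants stay open. Plant age, inseparable here too (0 mutant libraries overlap Col-0), and an effect of the AGO1 mutations stay open and untested.

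In the third pattern, the tissue change of some miRNAs differed between mutants and Col-0. Vascular RNA in epidermis libraries cannot be told apart for any of 13 values. In epidermis 4 of them (miR833a-5p in ago1-18, miR159a, miR158a-3p and miR403-3p in ago1-42) held at least 89.0% of the vasculature level. Mutant markers reached at most 43.8% (mean phloem 6.71% and 5.88%, xylem 15.1% and 7.22%). But by the library total miR159a and miR403-3p were no higher in Col-0 vasculature either (log2 -0.56 and -0.11). Against epidermal RNA in vasculature libraries, 5 of 15 values (miR167a-3p in both mutants and miR391-3p, miR167d and miR167a-5p in ago1-42) lay beyond the highest epidermis marker ratio (9.63% and 7.69%), but for the other 10 it cannot be told apart, since markers in vasculature rose from 0.181% of their epidermis level in Col-0 to 3.61% and 3.10%, near the 2.55% and 3.25% of miR165a-5p. Against a mislabelled sample, 2 of 2 libraries with differing title and label lay nearer to the title's group on 24-nt bins, Col-0 epidermis replicate 3 at 4.07 (title mean 4.35, label mean -3.90) and ago1-18 epidermis replicate 3 at 1.85 (2.57 and -2.87). A changed cell make-up (epidermis markers at 71.6 and 68.3 RPM in mutant epidermis, 286 in Col-0, no overlap, adjusted exact p = 0.132 each over both tissues), plant age and an effect of genotype in a tissue stay open and untested.

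Other splits of the libraries were counted for each number of calls. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. The real counts and the highest of the other splits for miRNAs were 89 and 0, 44 and 0 and 64 and 1 between tissues in Col-0, ago1-18 and ago1-42, 67 and 0 and 63 and 0 in ago1-18 vasculature and epidermis, and 67 and 0 and 60 and 1 in ago1-42. For 24-nt bins they were, in the same order, 234 and 0, 88 and 3, 553 and 35, 321 and 0, 348 and 0, 364 and 0, and 464 and 54, and for genes 727 and 0, 419 and 0, 511 and 17, 71 and 0, 208 and 1, 82 and 0, and 159 and 18. For the interactions, 12 of 100 splits gave as many as the 11 calls of ago1-18 (highest other 88) and 8 of 100 as many as the 21 of ago1-42 (highest other 77), so that chance is not excluded there. Splits with several times the real count mix tissues and genotypes. Of 41 drawn to balance these only the real one gave as many (highest other 0). As the others mix them within groups, adding spread, this decides nothing.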

How the results depend on the processing

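The fits without the 3 libraries richest in structural RNA, with the non-structural total as library size and with antisense reads only, and shares without structural and organelle reads, were added after the data were seen. The cause of a change was not tested unless stated.

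Grouped by genotype label, with 2 libraries moved by construction, the calls numbered 45 miRNAs between Col-0 tissues (89 grouped by title), 7 and 37 in ago1-18 and ago1-42 epidermis (63 and 60) and 1 and 3 in the interactions (11 and 21). There were 93 and 333 bins between Col-0 and ago1-18 tissues (234 and 88), 151 in ago1-18 vasculature (321), 0 in ago1-18 epidermis by edgeR (348; DESeq2 by title gave 673) and 96 in ago1-42 epidermis (464), and 318, 1 and 93 genes between Col-0 tissues and in ago1-18 and ago1-42 epidermis (727, 208 and 159). Without the 2 libraries of differing label, fewer samples gave 6 and 8 miRNA interactions, 118 bins and 370 genes between Col-0 tissues, 202 bins and 91 genes in ago1-18 epidermis, and 6 of 24 shares (14 with all).

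The non-structural total gave 86 and 99 miRNAs between ago1-18 and ago1-42 tissues (44 and 64) and 6 in the ago1-18 interaction. It gave 2863, 149 and 1284 bins (234, 88 and 553) and 313, 140 and 235 genes (727, 419 and 511) between Col-0, ago1-18 and ago1-42 tissues, and 45, 103, 52 and 81 genes in ago1-18 vasculature and epidermis and ago1-42 vasculature and epidermis (71, 208, 82 and 159). The library total gave 38 miRNAs in ago1-42 epidermis, 5 and 12 in the interactions, 135 bins between Col-0 tissues, and 182, 213, 202 and 288 bins in ago1-18 vasculature and epidermis and ago1-42 vasculature and epidermis (321, 348, 364 and 464). RLE factors kept each count within 1.5 times.

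DESeq2 gave 18 miRNAs in the ago1-18 interaction, 551, 407, 1286, 574, 673, 579 and 836 bins in the 7 comparisons, tissues first, and 336 and 296 genes in ago1-18 and ago1-42 epidermis. Only the compared groups gave 41 miRNAs and 261 genes between ago1-42 tissues, 6 in the ago1-18 interaction, and 359, 25 and 96 bins between Col-0, ago1-18 and ago1-42 tissues, with 540 in ago1-18 vasculature and 236 in ago1-42 epidermis. Without a filter on low counts there were 385, 452 and 537 bins between Col-0 and ago1-18 tissues and in ago1-18 epidermis and 384, 263 and 340 genes between the 3 pairs of tissues. Weighted multiple matches gave 449, 208 and 1189 bins between tissues. Exact mature sequences gave 34 miRNAs between ago1-42 tissues and 6 in the ago1-18 interaction. Antisense reads alone, fewer by construction, gave 96, 17, 116, 32, 54, 47 and 81 genes. Without the 3 libraries richest in structural RNA there were 4 and 9 miRNA interactions, 184 bins and 47 genes in ago1-18 vasculature, 176 genes between ago1-18 tissues and 112 in ago1-18 epidermis. Bins of 500 bp kept each count within 1.5 times.

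With an estimated correlation 4 of 37 miRNA list calls held and 12 of 14 gene list calls. The replicate numbers were not shown to pair the samples: in 0 of 21 comparisons were all 3 correlations of deviations over 0.1 (-0.373 to 0.364), and 24 of 63 libraries fitted their own number best. Between tissues all miRNA correlations were positive (0.0420 to 0.273), while those of bins and genes took both signs, so that a weak pairing of tissues stays open. The replicate block moved 24-nt calls between ago1-18 tissues to 135 from 88, gave 13 of 24 shares against 14, left 37 and 14 list calls and moved no other count by over 1.5 times.

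Leaving out 1 library gave, in the 7 comparisons with tissues first, 67 to 79, 32 to 45, 44 to 57, 54 to 65, 52 to 60, 61 to 67 and 40 to 57 miRNAs and 6 to 14 and 11 to 27 in the interactions. It gave 81 to 255, 16 to 107, 142 to 665, 188 to 262, 182 to 290, 242 to 293 and 253 to 550 bins and 352 to 658, 219 to 295, 290 to 496, 45 to 79, 104 to 159, 61 to 96 and 61 to 174 genes. Shares gave 0 without any replicate number, where the smallest exact p was 0.0556 for the mutant tests (36 arrangements) and 0.00926 for the tissue tests (216). Counts moved by over 1.5 times as follows. The ago1-18 interaction gave 7 without Col-0 epidermis replicate 3 and 6 without ago1-18 epidermis replicate 1, and that of ago1-42 13 without Col-0 epidermis replicate 3 or ago1-42 epidermis replicate 2 and 11 without ago1-42 vasculature replicate 3. Bins between Col-0 tissues numbered 81, 90 and 125 without vasculature replicate 2 or 3 or epidermis replicate 3, between ago1-18 tissues 16, 30 and 36 without vasculature replicate 1 or 3 or epidermis replicate 2, and between ago1-42 tissues 289, 172, 252 and 142 without vasculature replicate 1, 2 or 3 or epidermis replicate 2. In ago1-18 vasculature they numbered 188, 190, 198 and 209 without Col-0 replicate 2 or 3 or ago1-18 replicate 1 or 3, in its epidermis 188, 182, 203 and 193 without Col-0 replicate 1, 2 or 3 or ago1-18 replicate 2, in ago1-42 vasculature 242 without Col-0 replicate 2 and in its epidermis 274, 267 and 253 without Col-0 replicate 1 or 2 or ago1-42 replicate 2. Genes between Col-0 tissues numbered 352 and 384 without vasculature replicate 2 or 3 and 437, 433 and 379 without epidermis replicate 1, 2 or 3, between ago1-18 tissues 234, 279 and 276 without vasculature replicate 1, 2 or 3 and 250 and 219 without epidermis replicate 1 or 2, and between ago1-42 tissues 338 and 290 without vasculature or epidermis replicate 2. They numbered 45 in ago1-18 vasculature without its replicate 3, 120, 104 and 134 in ago1-18 epidermis without Col-0 replicate 3 or ago1-18 replicate 1 or 2, and 61 in ago1-42 epidermis without its replicate 2.

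Between tissues, values turned by the library total for miR403-3p (-0.11), miR159a (-0.56) and miR395a (-0.20) in Col-0 and miR403-3p (-1.08) and miR165a-3p (-2.49) in ago1-18, among the values followed through each setting. By the non-structural total they turned for miR156a-5p (-1.34) and miR159a (-0.24) in Col-0, miR168a-5p (-1.45), miR162a-3p (-1.61), miR403-3p (-1.11), miR165a-3p (-1.92) and miR156a-5p (-1.94) in ago1-18, and miR168a-5p (-1.17), miR162a-3p (-1.16), miR156a-5p (-1.22) and miR395a (-1.71) in ago1-42. Grouping by label turned miR403-3p (-0.16) and miR165a-3p (-4.06) between ago1-18 tissues, miR398b-3p in ago1-18 epidermis (0.17) and miR822-5p in the ago1-18 interaction (-0.32). Exact sequences turned miR160c-3p in ago1-18 vasculature (-0.26) and in ago1-42 vasculature (-0.72) and epidermis (-0.89). Counting distinct sequences turned the tissue difference of the passenger share (0.457 points) and the mutant differences of the miRNA share (0.00929 and 0.0383), and leaving out structural reads turned the tissue difference of the 5' U share (-0.759). In Col-0, miR166e-5p (1.44) also turned negative by both totals. By RLE factors no value followed turned.

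Small changes were often missed: on simulated data for Col-0 tissues, 2-fold changes were recovered for 20% of miRNAs, 7.69% of bins and 1.54% of genes, and 16-fold ones for 100%, 80.6% and 85.9%. Whether depth or the spread between replicates (median chi-square per degree of freedom 9.28 and 17.01 for miRNAs in Col-0 vasculature and epidermis) sets this limit was not tested.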

Other observations

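Some 24-nt bins were filled in a genotype and near 0 in another. The bin on chromosome 1 from 18736001 held 383 to 495 scaled RPM in the 6 ago1-18 libraries, 0 in 5 Col-0 libraries and 3.40 in Col-0 epidermis replicate 3, and up to 14.8 in ago1-42. The bin on chromosome 1 from 23586001 at AT1G63615 held 0 in the 6 Col-0 libraries, 51.0 to 99.6 in ago1-18 and 37.7 to 101 in ago1-42. The bin on chromosome 1 from 23755001 at AT1G64035 held 262 to 703 in Col-0, 299.8 to 717 in ago1-18 and 0 to 17.5 in ago1-42. No explanation was tested.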
